A study of Mus musculus with 2 samples.

How the data were processed

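Chromatin immunoprecipitation from W4 mouse embryonic stem cells was measured on 2 NimbleGen promoter arrays of the mm8 build, each with 1 Sall4 and 1 IgG precipitate in different dyes, per the labels. Both arrays form 1 group, and replicate numbers follow accession order and pair nothing. Per the labels, both had the same dye orientation, so a dye effect does not cancel in their mean.

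Intensities and log2 values were used. The scanner intensity of each probe in the green channel (the shorter wavelength, at which Cy3 is read) and the red channel (Cy5) is given on a linear scale per the file headers, which name NimbleScan 2.3.78 for the separate files of array 2, whose values were identical to those of its joint file. No background or dye correction is stated. The deposited value table holds log2 values, and the authors' steps for it are not given in the sources used here. Compared with the scanner values it equalled log2(red/green) minus 1 constant per array within 0.00502, with a median of 0 in each column, so its scale, centring and order of channels are known, while which channel held Sall4 is not.

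From the intensities, log2(red/green) was computed per probe with no background subtraction, loess or quantile step, and each array was centred on the median of its 380409 promoter probes, which was 0.09 on array 1 and 0.20 on array 2 before centring. Saturated probes (81 to 151 per channel) were kept. The probes of a region were averaged where it had at least 4. All 17354 regions did, the fewest being 5, so this minimum removed none. The mean over both arrays was tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment at 0.05 over all regions. SE is the moderated standard error. The test's prior had 18.4 degrees of freedom, beside 1 residual degree. Centring removes a common offset of promoter probes. A called region therefore departs from the median promoter probe, and not from an absolute absence of enrichment. The median region mean lay slightly on the red side of that probe, at 0.03.

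The fit was checked on 20 simulated data sets of 17354 regions on 2 arrays with the estimated spread, in which 200 regions changed. It recovered 99.95% of changes of 0.4 and 100% of changes of 0.8 on the log2 scale, each size in 100 regions. Both sizes are many times the median SE of 0.05, so near-complete recovery was to be foreseen. Smaller changes were not simulated, though the median called region had a size of 0.24 and the smallest 0.13. The simulated arrays were drawn independently, with no probe or dye effect shared by both. A mean of 26.3 unchanged regions was called (5 to 48), 11.6% of all calls, which is above the nominal 5%. The cause of this excess was not tested. The share belongs to simulations with few changed regions and is no error rate for calls in the measured data.

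Windows were means of 5 adjacent probes of a region, counted where both arrays passed 1 or both passed -1. They were set against 100 reassignments of the probes within 10 classes of brightness, the pair of array values of a probe kept together. Brightness is the mean log2 intensity over both channels and arrays. Correlations of the arrays, the overlap of the highest and lowest 5% of regions, and position profiles in 250 bp bins were descriptive. Classes of length and chromosome were compared with Fisher's exact test or a permutation test in scipy 1.17.1. Classes of brightness were described with Wilson intervals and not tested. All of these classes were chosen after the data were seen. Tables were handled with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.

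The comparison, its test and the rule for named regions were fixed before the data were examined. The rule takes the 10 highest and 10 lowest mean ratios among regions past the threshold with the same sign on both arrays. It also asked for a gene symbol per region and for members of gene lists. The files pair regions with coordinates only, and the gene table at hand is of the GRCm38 assembly, to which mm8 coordinates were not converted. Gene names were therefore not assigned, the symbol condition was dropped, and the gene lists were not analysed here.

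Alternatives covered normexp background correction with offset 50, loess, a common scale, the median or strongest window in place of the mean, other probe minimums, the dimmest 25% of probes left out, the deposited table, other variance models, window lengths and thresholds, and each array alone. A test against a log2 change of 0.32 (limma's treat), centring on random probes, a shift of both arrays by the mean of those centres and subtraction of medians over 32 by 32 blocks of the slide were added after the data were seen. The slide layout of array 2 was used for both arrays. Without 1 of the arrays no residual degree of freedom is left, so single-array values carry no test.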

Results

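Occupancy of promoters by Sall4, a zinc-finger transcription factor of pluripotent cells, was measured in W4 cells, a mouse embryonic stem cell line grown with LIF and given no treatment. DNA recovered with a Sall4 antibody and DNA recovered with control IgG were labelled with different dyes and hybridised together to a promoter tiling array (ChIP-chip), so each array carried its own comparison of Sall4 with IgG. The comparison asks which promoters held more DNA in the Sall4 precipitate than in the control. There were 2 arrays, named array 1 and array 2, in 1 group. The labels do not say that they came from separate cultures. Every limma p-value and SE therefore rests only on the spread between these 2 arrays, which may be technical. In the main test that spread was pooled mostly over regions, with 18.4 prior degrees of freedom beside 1 residual degree. The number of arrays limits the precision. Tests that compare classes of regions take regions as units and do not measure that spread. Each array held 380409 probes in 17354 promoter regions of the mm8 build, with a median of 22 probes per region spaced a median of 100 bp apart. Of the regions, 15901 were 2500 bp long and 1451 were longer. The median promoter probe read 1447 in the green and 1668 in the red channel on array 1, and 2240 and 2628 on array 2, in scanner intensity units. Random control probes, which match no promoter, had medians of 504 and 438.0 on array 1 and 664 and 811 on array 2.

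The labels left the direction of the ratio open. They gave the Sall4 sample Cy5, the dye read in the red channel (the longer wavelength), together with a source name that carried the wavelength of the green channel, in which Cy3 is read. They gave IgG the reverse. The deposited value table placed red on top. On the basis of the dye label and that table, higher in red was the likely side of Sall4 enrichment, but the source names say the opposite and no array had the dyes swapped. The sides are therefore named by channel, and with the sign turned every value and count below changes sides. Regions are given by mm8 coordinates, as in the files, and no gene was assigned to any of them.

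The promoter region highest in red was chr7:49504356-49506856, with a mean log2(red/green) of 1.35 ± 0.07 (moderated SE, n = 2 arrays), a 2.55-fold difference. Its values were 1.55 on array 1 and 1.14 on array 2 over 22 probes. The moderated SE comes mostly from the spread pooled over regions and does not show how far apart the arrays lay at a single region. Next came chr7:29285634-29288134 at 1.18 ± 0.08, chr7:4327838-4330338 at 1.07 ± 0.07 and chr15:56524087-56526587 at 1.03 ± 0.06. Chromosome 7 held 4 of the 10 highest regions, the last of them chr7:5823364-5825864 at 0.97 ± 0.06. It also held the most regions of any chromosome, 1541 of 17354. Its share of regions called higher in red, 31.5%, was not above the 32.5% over all regions. The other members of the 10 highest lay on chromosomes 17, 11, 5 and 6, and chr5:78076829-78079329 closed the list at 0.90 ± 0.06. At chr17:37690529-37693029 array 2 (0.97) read above array 1 (0.92). At the other 9 of these regions array 1 gave the larger value, as it did in spread over all regions, where the SD of region means was 0.26 on array 1 and 0.22 on array 2.

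On the opposite side, chrX:66644468-66646968 had the lowest mean, -0.98 ± 0.05 (moderated SE, n = 2 arrays), with -0.93 on array 1 and -1.04 on array 2 over 15 probes. It was followed by chr18:77251246-77253746 at -0.90 ± 0.05, chr14:100525701-100528201 at -0.85 ± 0.05 and chr17:46964978-46967478 at -0.84 ± 0.05. The 10 lowest regions ended with chr16:4704663-4707163 at -0.76 ± 0.05. By limma with Benjamini-Hochberg adjustment, the adjusted p of the 20 named regions ran from 7.83e-10 to 1.07e-08, and each had the same sign on both arrays, as the rule of selection required. In simulated data with few changed regions, 11.6% of the calls of this test were false. That share depends on how many regions change, so it is no error rate for the named regions. The share of false calls in the measured data was not estimated. The lowest region was smaller in size than the highest, 1.98-fold against 2.55-fold.

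**Figure D1:**
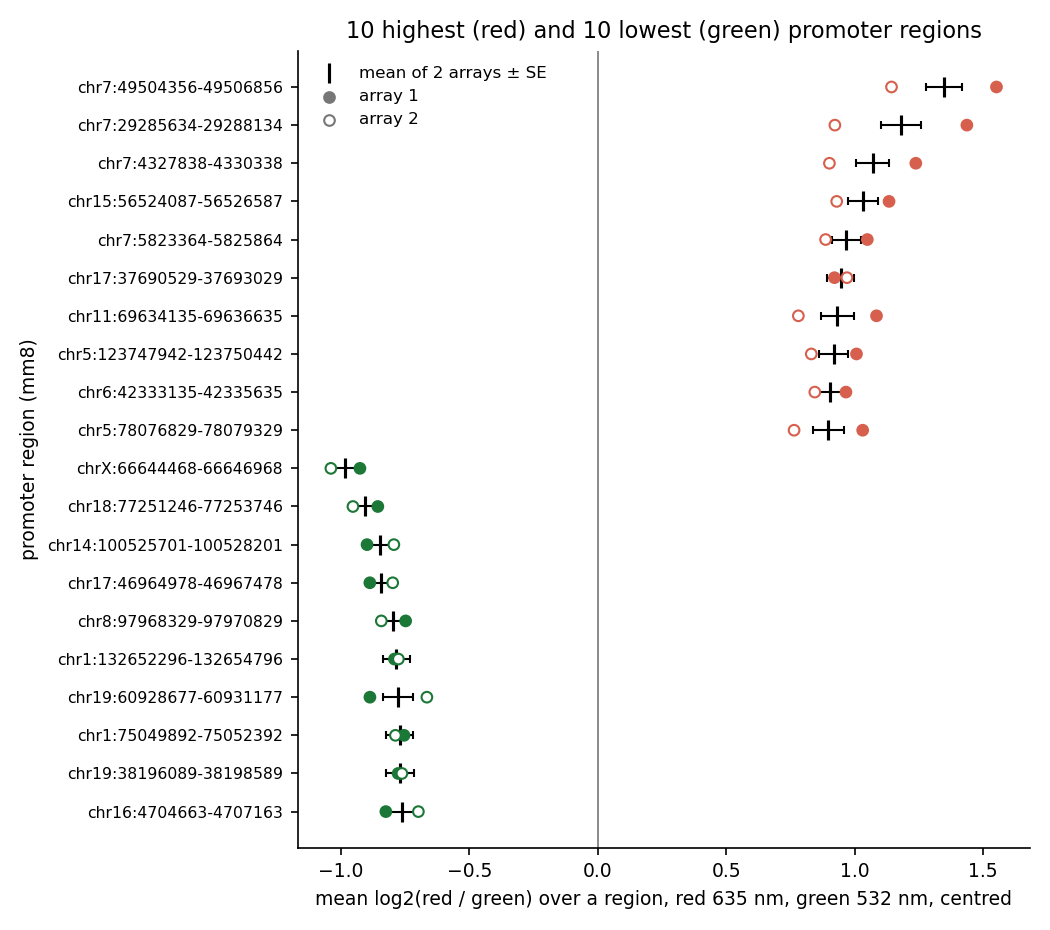
Mean log2(red / green), median-centred, of the 10 highest (red) and 10 lowest (green) promoter regions, with mm8 coordinates on the vertical axis. Filled points are array 1, open points array 2, and black bars the mean of both arrays ± moderated SE, from -0.98 for chrX:66644468-66646968 to 1.35 for chr7:49504356-49506856. The moderated SE rests mostly on a spread pooled over regions.

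Over all 17354 regions, 5647 were higher in red and 4086 were higher in green at a limma adjusted p under 0.05, together 56.1% of regions. At an unadjusted p under 0.05 the counts were 6067 and 4484. Most of these differences were small. The median called region had an absolute mean of 0.24, or 1.18-fold, and the smallest 0.13. Tested against a log2 change of 0.32 in place of 0, 426 regions were higher in red and 153 in green. Only chr7:49504356-49506856 passed a log2 value of 1 on both arrays, and 0 regions passed -1 on both. The balance of the calls depended on the centring and on other settings. Of the called regions 58.0% were higher in red, and the median of all region means was 0.03. The share was 51.5% with dim probes left out and 53.8% with the median over probes. Centring each array on its random control probes left 342 regions higher in red and 6 in green, a share of 98.3%. That centring moved the median region by 0.12 and also set the arrays 0.37 apart, and limma's prior SD rose from 0.08 to 0.28. With both arrays shifted alike by that 0.12, a setting added after the data were seen, 9389 regions were higher in red and 1760 in green, a share of 84.2%. The means of named regions on the green side stayed below 0 when each array was centred on its random probes, but 4 of the 10, among them chr16:4704663-4707163, no longer passed the test.

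In 960 regions at least 1 window of 5 adjacent probes had a mean log2(red/green) over 1 on both arrays, and in 497 regions at least 1 window lay under -1 on both, with 14 regions in both sets. The windows named here were chosen by value after the data were seen. The highest, from 166998748 to 166999148 on chromosome 1, read 2.57 on array 1 and 2.56 on array 2. Another on chromosome 16, from 37833934 to 37834334, read 2.81 and 2.31, and 1 on chromosome 10, from 93261279 to 93261679, read 2.36 and 2.20. The lowest lay on chromosome X, from 9640874 to 9641274, at -2.09 and -2.19. The next, on chromosome 19 from 34232640 to 34233040, read -1.86 and -1.84. Inside the highest whole region, chr7:49504356-49506856, the strongest window read 1.92 and 1.33. Reassigning probes among positions of like brightness 100 times gave a mean of 17.9 regions with a red window (9 to 30) and 2.86 with a green window (0 to 8). The counts rested on both arrays. Without array 2, array 1 alone gave 2382 and 937 regions, and without array 1, array 2 alone gave 1094 and 620.

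Long tiled regions leaned to the green side. Of the 1451 regions over 2500 bp, 326 (22.5%) were higher in red, against 5320 (33.5%) of the 15901 regions of 2500 bp (p = 1.53e-18, Fisher's exact test, two-sided). The shares higher in green were 28.9% and 23.1% (p = 1.02e-06, Fisher's exact test, two-sided). The medians of the classes differed by -0.05 on the log2 scale on each array (permutation test over regions, 100000 draws, two-sided p = 1e-05, the smallest they can give). Regions are not independent replicates, and these tests describe the regions of 2 arrays.

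The share of calls also changed with brightness. In the dimmest 25% of regions 37.9% (95% Wilson interval 36.5 to 39.4) were higher in red and 14.3% (13.3 to 15.3) in green. In the brightest 25% the shares were 26.7% (25.4 to 28.0) and 31.1% (29.7 to 32.5). Loess on brightness subtracts a trend of the ratio with brightness by construction, so it cannot test whether this difference holds. After loess these classes had 36.4% and 37.6% of regions higher in red. Each other setting compared kept the dimmest class above the brightest. The shares were 39.5% and 27.6% with normexp, 24.9% and 17.1% with the median over probes, and 39.0% and 27.6% with slide blocks. With random-probe centring, where few regions were called, they lay close together, at 1.94% and 1.73%.

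**Figure D2:**
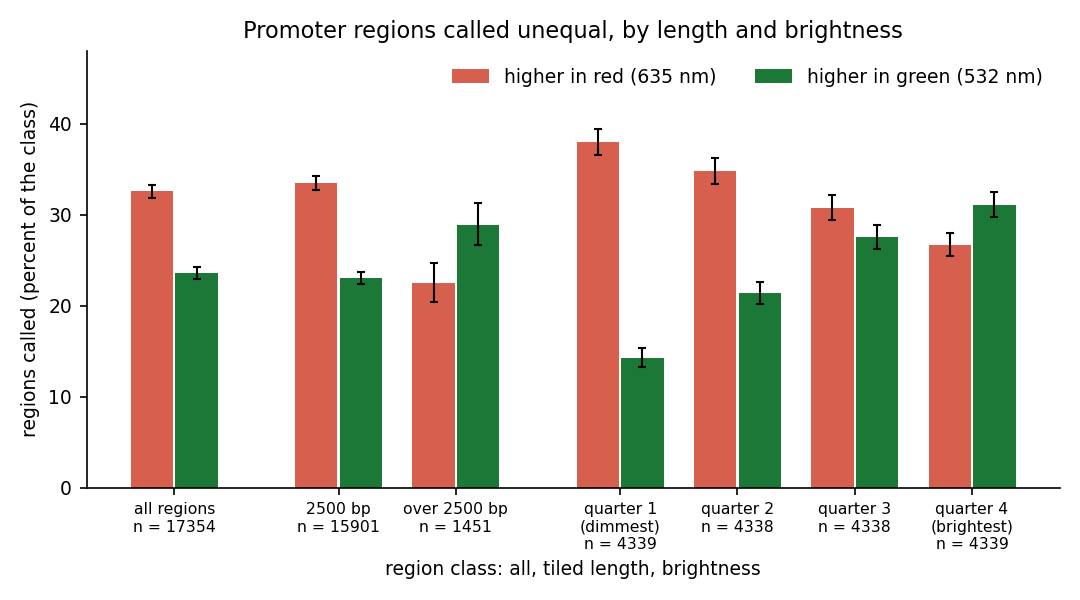
Percent of promoter regions called higher in red (red bars) or in green (green bars) by the limma test, among all regions, by tiled length and in 4 equal classes of mean brightness, with 95% Wilson intervals as error bars and the number of regions under each class. The red bar falls from 37.9% in the dimmest class to 26.7% in the brightest class, and is 22.5% in regions over 2500 bp.

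Among 20 chromosomes tested, 3 had a share of regions higher in red that departed from that of the remaining regions, the share over all regions being 32.5% (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted). Chromosome 6 had 37.4% (adjusted p = 0.0170) and chromosome 3 had 37.1% (adjusted p = 0.0280). Chromosome 8 had the lowest share, 27.6% (adjusted p = 0.0187). None of these held under every setting. With the median over probes in place of the mean, the adjusted p was 0.463 for chromosome 6, 0.271 for chromosome 3 and 0.118 for chromosome 8. After loess it was 0.104, 0.208 and 0.0122. Over 14 settings it ranged from 0.00206 to 1 for chromosome 6, from 0.0116 to 0.857 for chromosome 3 and from 0.00410 to 1 for chromosome 8. For regions higher in green, 0 chromosomes passed, with 3 at an unadjusted p under 0.05. The lowest adjusted p of Fisher's exact test on that side was 0.0768, on chromosome 8.

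The 2 arrays ranked promoter regions alike. Across regions Pearson's r was 0.896 and Spearman's rho 0.882, and across single promoter probes they were 0.778 and 0.727. Regions and probes are not independent replicates, so no p is given. Of the 868 regions in the highest 5% of each array, 555 (63.9%) were shared, and of the lowest 5%, 590 (68.0%), where independent lists would share 43.4. The sign was the same on both arrays in 85.2% of regions, and the median absolute difference between the arrays was 0.07 on the log2 scale.

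**Figure D3:**
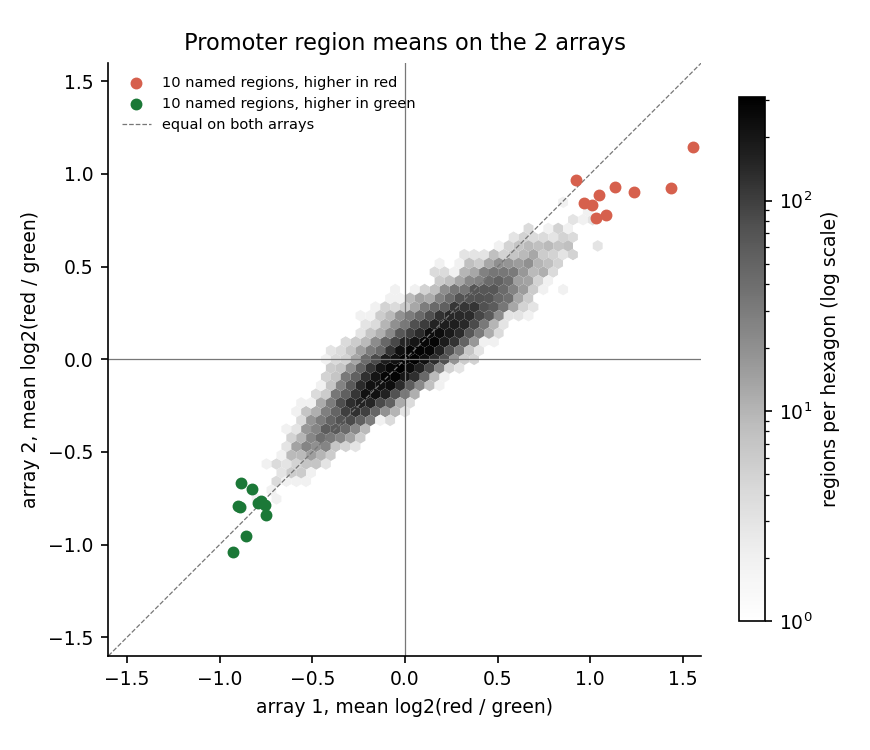
Mean log2(red / green) of each of 17354 promoter regions on array 1 (horizontal axis) and array 2 (vertical axis), as hexagons shaded by the number of regions on a log scale, with the 20 named regions as red and green points and the line of equal values dashed. Regions lie along the diagonal, with r = 0.896.

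Random control probes served as the background, as they match no promoter, but what DNA the bright ones among them bound was not tested. Between 42.3% and 60.6% of promoter probes were brighter than the 95th percentile of random probes of the same channel. Over all 8898 random probes the ratios of the 2 arrays correlated with r = 0.128. Among the 229 random probes brighter than the promoter median in all 4 channels, r was 0.834 (95% bootstrap interval 0.783 to 0.869), against a mean of 0.853 (0.735 to 0.906) in 100 draws of promoter probes of the same brightness. Their covariance between arrays was 72.2% of that of these promoter draws, and in each of 8 classes of brightness r was lower for random than for promoter probes. Spearman's rho was lower in 7 of them, and in the brightest it was 0.874 for random and 0.863 for promoter probes.

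**Figure D4:**
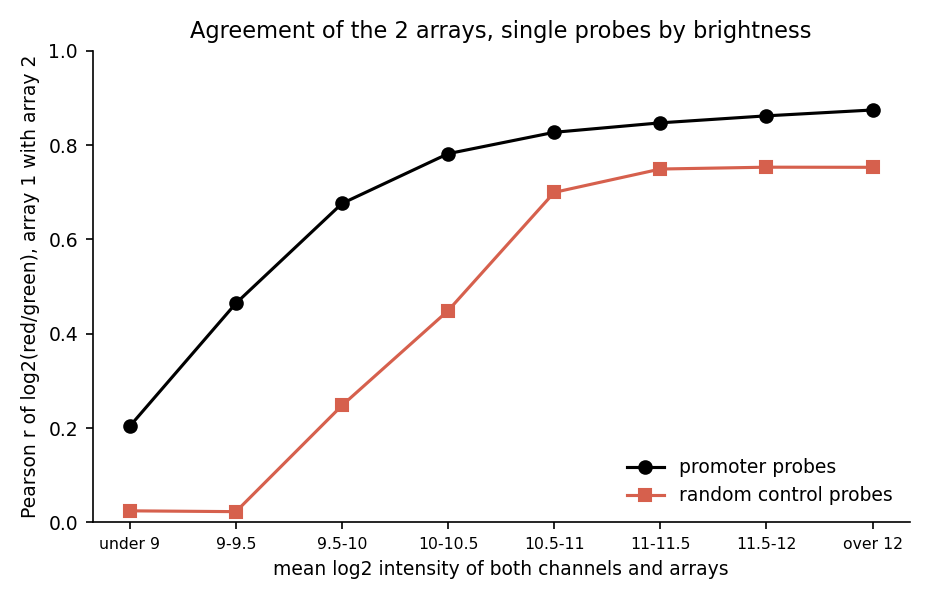
Pearson's r between the arrays of log2(red / green) of single probes, by class of mean log2 intensity, for promoter probes (black circles) and random control probes (red squares). Promoter probes rise from 0.204 in the dimmest class to 0.874 in the brightest, and random probes from 0.0244 to 0.753.

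Along the tiled region the mean ratio was almost flat. In 10 bins of 250 bp across the 2500 bp regions, the mean of both arrays varied over a range of 0.03 on the log2 scale. The bin means lay between 0.03 and 0.06 on array 1 and between 0.01 and 0.04 on array 2. The files give no strand for a region, so opposite orientations were averaged and the position of the transcription start was not used here.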

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

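The tests of bright random probes, of shuffled region means and of flanking probes were chosen after the result was seen, the test of slide position was added after the data were seen, and that of loess was chosen before. The 229 random control probes brighter than the promoter median in both channels of both arrays, 2.57% of the random probes, drew attention because they lie outside the promoter measurement yet carry signal above that of most control probes. Their median ratio was -0.14 on array 1 and -0.25 on array 2, against -0.02 and -0.16 in promoter probes of the same brightness.

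The pattern to which they speak is the close ranking of promoter regions by the 2 arrays (r = 0.896). A trend of the ratio with brightness and position on the slide are argued against as the whole cause, since r was 0.944 after loess and 0.900 after subtraction of block medians. Probe effects not tied to promoter DNA may account for much of the likeness of single probes. The bright random probes correlated with r = 0.834 at 72.2% of the covariance of like promoter probes, though what DNA they bound was not tested. Independent probe effects do not explain region means, whose covariance was 4.25 times that of shuffled probes. Sall4 occupancy stays open and cannot be told apart from sequence-dependent dye effects shared by neighbouring probes, because both arrays had the same dye orientation. The difference of each probe from its flanking probes correlated with r = 0.493 between arrays, which measures effects of single probes only and decides nothing about what neighbours share, and base composition of the probes was not tested here.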

How the results depend on the processing

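The tests against a log2 change of 0.32, with random-probe centring, with a common shift and with slide blocks were chosen after the data were seen. The lists of gene names could not be matched to regions, so their alternatives were not run. A minimum of 1 probe changed nothing. The median promoter probe was 2.87 to 3.81 times the median random probe, and leaving out dim probes gave 4738 and 4455 calls, within 1.5 times of the main counts. The cause of the shifts below was not tested except where the alternative's own construction gives it.

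The 5647 regions higher in red became 3738 with the median over probes, and 9460 with the strongest window, which also gave 7504 in place of 4086 in green. The test against 0.32, a stricter null, gave 426 and 153, random-probe centring 342 and 6, a common shift of both arrays by its mean 9389 and 1760, and a rule of both arrays past 1 gave 1 and 0. Single arrays gave 1 to 16 regions past 1 and 0 to 1 past -1. With the sign turned the counts were 4086 and 5647. Other settings stayed within 1.5 times. Of 280 values of the 20 named regions under 14 settings, 276 kept direction and call, 4 kept direction only, all with random-probe centring, and 0 reversed. These regions were picked as the extremes of the same data. Their means were unchanged by the probe minimums, the variance models and the test against 0.32, so this count is no independent support. The share on chromosome 3, above that of all regions, fell below it with the test against 0.32 (2.19% against 2.45%) and random-probe centring (1.46% against 1.97%).

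The correlation of arrays was 0.918 with normexp, 0.944 with loess, 0.940 without dim probes, 0.798 with the median over probes and 0.900 with slide blocks. The share of highest regions in common was 67.2%, 74.7%, 71.0% and 50.3% under the first 4 of these, and 70.0% for the top 10%. For lowest regions it was 73.3% with loess, 74.8% without dim probes, 56.0% with the median and 56.9% for the lowest 1%.

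Regions with a window were 2183 and 1332 (red and green) with 3 probes, 415 and 199 with 7, 6056 and 4978 at threshold 0.5, 80 and 22 at 1.5, and 2668 and 1130 with normexp. Loess left 329 in green. Single arrays gave 1094 to 2382 and 620 to 937. The range of position bins was 0.0234 with loess and 0.0275 to 0.0285 on single arrays.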

Other observations

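The tests of loess on window counts and of the ratio of shuffled windows were chosen after their results were seen, and the other tests of this part before, while the values of chromosomes X and Y were picked after the data were seen. Promoter probes on chromosome X had a lower median intensity than those of every autosome in all 4 channels. Their median intensity was 76.1% of the autosomal median in green and 74.9% in red on array 1, and 77.9% and 79.1% on array 2. The log2 median of X minus that of chromosome 2, the dimmest autosome, was -0.28 in green and -0.30 in red on array 1, and -0.22 and -0.21 on array 2. The share of X regions higher in red, 34.0%, did not depart from the rest (Fisher's exact test, two-sided, adjusted p = 0.549).

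The 15 regions on unplaced sequence of chromosome Y were among the brightest of the array and fell into 2 sets by value. In 6 of them the mean log2(red/green) was 0.63 to 0.76 at a log2 brightness of 14.0 to 14.7, and in the other 9 it was -0.17 to 0.25 at 15.1 to 15.6. These sequences occur in many near-identical copies, so the values of single regions are uncertain. They also lie near the scanner's ceiling, with 2 of 99 probes of the first set and 26 of 182 of the second saturated in at least 1 channel, and ratios shrink where both channels saturate, so the sets are not shown to differ in the DNA recovered. Of the 10 regions on placed chromosome Y, 6 were higher in red and 1 in green.

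Regions with a red window outnumbered those with a green window, 960 to 497, and a trend with brightness is argued against as the whole cause, since the ratio of the counts was 2.85 after loess. Shuffled probes gave 6.26 red windows per green window, above the observed ratio of 1.93. Skew of single probes towards red may thus contribute to the imbalance. The shuffles keep the measured ratios, whatever caused their skew, so they cannot weigh skew against enrichment of DNA in red. The shuffled ratio cannot show that skew is enough, because shuffled windows were few. The observed ratio also depended on the threshold, with 1.22 at 0.5 and 3.64 at 1.5. The excess over shuffles, 53.7 times in red and 174 times in green, shows clustering on both sides. No shuffle gave more than 30 regions with a red window, which argues against skew without clustering as the source of the 960. How skew and clustering together set the balance was not tested. The hypothesis that promoter DNA was enriched in the channel read in red, which may be the Sall4 channel, remains open. Among bright random probes past 0.5 on both arrays, 45.2% (14 against 17 on the green side, 95% exact interval 27.3 to 64.0) were on the red side, but promoter probes of the same brightness had no excess either (46.7%, 32.4 to 60 in 100 draws), so single probes could not decide.

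Regions over 2500 bp lay lower than 2500 bp regions, with a difference of medians of -0.05 on the log2 scale. A trend with brightness is argued against as the whole cause, since the difference was -0.0458 after loess, and so is the number of probes averaged, since it was -0.0505 with at most 20 probes drawn per region, where the classes had medians of 22 and 31 probes. The number of probes tiled is another matter, chosen after the data were seen. The median of 2500 bp regions fell from 0.05 with 15 to 19 probes to -0.01 with 25 to 29. With 20 to 24 probes the median of longer regions was 0.03, as in 2500 bp regions with as many. With 15 to 19 probes longer regions stayed lower (-0.003, 64 regions), as they did with 25 to 29 (-0.046, 284 regions). The number of probes tiled was therefore not shown to account for the difference. A biological explanation was not tested, since the files give no genes or strands for these regions.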
